A study of Homo sapiens with 18 samples.

How the data were processed

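Transcript levels were measured by RNA sequencing in 18 libraries of Jurkat E6-1 cells, a human leukaemic T cell line grown in RPMI-1640 with fetal bovine serum, per the labels' protocols. The labels put 3 libraries in each of 6 groups: DMSO, SP100030, selinexor, PMA with ionomycin, and PMA with ionomycin given together with either compound. The compounds and ionomycin were used at 1 uM and PMA at 50 nM, all added at the same time, and cells were collected after 6 hours. Total RNA was extracted with an RNeasy kit and polyadenylated RNA was selected, per the labels' protocols. One label gives peripheral blood mononuclear cells as the source while the cell line label gives Jurkat; the cells are called Jurkat here. The labels number the replicates 1 to 3 in each group and do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

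The authors deposited a table of TPM, a length-corrected share of a library's transcripts, per gene symbol. The submitters' processing notes name kallisto 0.46.1, edgeR and the genome build hg38, without saying what each was used for or how transcripts were summed to genes. The table has 35545 entries, of which 27 have names turned into dates by a spreadsheet and 2 have duplicated names. Library totals lay between 934081 and 941370 TPM. TPM keeps no read depth, so the depth of each library is unknown and no interval for counting error is given. Of 14141 tested genes, 13050 matched a symbol of the GENCODE release 29 annotation on GRCh38 (hg38), from which the coordinates and exon numbers are taken. Genes with near-identical copies (CCL3 and CCL3L3, CCL4 and CCL4L2, XCL1 and XCL2, HSPA1A and HSPA1B), pseudogenes and receptor V segments are reported as uncertain, because reads can be assigned to the wrong copy. Whether strand was used is not given in the sources used here, so antisense and overlapping genes are uncertain too.

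Genes with at least 1 TPM in at least 3 of the 18 libraries were kept, which left 14141. The values were transformed to log2(TPM + 1), and a fold change given here is a difference on that scale, which understates the change of genes with low TPM. All 18 libraries entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend) with 1 mean per group and no covariate. Tests were two-sided and adjusted over the 14141 genes by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. There were 9 comparisons: 5 of a treated group with its own control, 2 of SP100030 with selinexor in the same state, and 2 interactions, each of which tests whether the effect of a compound differs between activated and resting cells. Activated means given PMA with ionomycin, and resting means not given them, in a growing cell line. All agents were added together, so no cells were activated before a compound was given. Values are printed as mean TPM ± SD (n = 3), and log2 changes as the change ± SE. A gene listed at 0 in a group is given no fold or interaction value against it.

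The design, the gene lists and the rule for the named genes were chosen before the data were examined. The rule names a panel of 12 genes in each comparison (XPO1, IL2, CD69, IL2RA, TNF, EGR1, NR4A1, MYC, NFKBIA, RCAN1, ARRDC3 and CDKN1A). It adds, in the 7 comparisons of 2 groups, the 6 highest and 6 lowest changes among genes past the threshold whose mean reached 5 TPM in the higher group and whose 3 values did not overlap those of the other group, so that these genes moved the same way in 3 of 3 libraries. For the interactions it adds the 4 highest and 4 lowest with a mean of 5 TPM in any of the 4 groups, without the overlap criterion. From each gene list it takes up to 4 members, 2 highest and 2 lowest past the threshold, or the one with the lowest p. Entries with no gene symbol, clone-type names, Y-linked genes and XIST were skipped, and some genes that the rule names are not reported here.

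The 26 gene lists hold 597 genes: cytokines and chemokines, surface activation markers, activation transcription factors, NF-kB targets, MAPK feedback genes, calcineurin and NFAT genes, T cell receptor and identity genes, nuclear transport, p53 targets, FOXO and quiescence genes, NRF2 targets, heat shock, the endoplasmic reticulum unfolded protein response, ATF4 and the integrated stress response, interferon-stimulated genes, the BCL2 family, G1/S and G2/M cell cycle genes, cholesterol synthesis, glycolysis, ribosome biogenesis, mitochondrially encoded genes, and markers of B cells, monocytes, NK cells, and erythroid and epithelial cells. Of these, 24 had at least 5 tested genes and were tested with camera from limma (two-sided, preset correlation 0.01), adjusted over the 216 tests of 24 lists in 9 comparisons. A second run estimated the correlation within each list. Of 55 list calls, 10 held with an estimated correlation: cytokines, surface markers, transcription factors, NF-kB targets, MAPK feedback genes and the unfolded protein response under activation, cytokines, surface markers and NF-kB targets in the selinexor interaction, and cytokines in the SP100030 interaction. Member counts are given over all genes tested and adjusted over the list alone.

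The replicate numbers were checked for pairing by correlating the deviations of libraries from their group means over the tested genes. The correlation was above 0.1 in each of 45 pairs of libraries with the same number, with a lowest value of 0.153 and a median of 0.439, against a median of -0.367 for libraries with different numbers. The labels give only the numbers, so any pairing comes from the data. Deviations within a group cancel out, so a shift shared by replicate 3 alone moves replicates 1 and 2 the opposite way. That gives positive same-number correlations even without pairing of replicates 1 and 2, where they ran from 0.153 to 0.540. For 17 of the 18 libraries the closest partner had the same number, which such a shift alone does not require. Correlations of replicate 1 with replicate 2 were not separated out, so the pairing of these is less certain than that of replicate 3. A fit with the replicate number as a block was made beside each result. The 6 libraries of replicate 3 deviated together most closely, with correlations from 0.536 to 0.780.

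Alternatives were a fit of only the groups compared, the replicate block, a pseudocount of 0.1, no filter, a minimum of 5 TPM, median-ratio and quantile scaling, no intensity trend, a minimum log2 change of 1, and leaving out each library in turn. A fit of replicates 1 and 2 only, a fit with liver and kidney marker scores as covariates and list tests with a pseudocount of 0.1 were chosen after seeing the data. Because both compounds were compared with the same controls, the correlation and the overlap of their effects are given beside values from 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. The 3 controls cannot be split into parts of 2 libraries. The limma step was tested on simulated data for the activation comparison over 14141 genes, where it recovered 63% of 100 genes changed by a log2 of 1 and 96% of 100 genes changed by a log2 of 2, with 3.64% false calls. The changed genes were drawn only from those well above 0 in DMSO. The noise was independent, with the same spread in each group. These rates therefore do not cover genes near 0 in DMSO, such as IL2, or shifts shared by a replicate number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.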

Results

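RNA was sequenced from Jurkat E6-1 cells, a human leukaemic T cell line, in 18 libraries of 6 groups with 3 libraries each. Cells were treated for 6 hours with the vehicle DMSO, with 1 uM SP100030 or with 1 uM selinexor, each alone or together with 50 nM PMA and 1 uM ionomycin. PMA is a phorbol ester that activates protein kinase C and ionomycin is a calcium ionophore, and together they activate T cells without engaging the T cell receptor. Selinexor inhibits XPO1 (CRM1), the main export receptor for proteins leaving the nucleus, and SP100030 is known here by its code name. The series title names the effect of XPO1 inhibition on Jurkat activation as the subject. Levels are in TPM, and each library held 12196 to 13374 genes at 1 TPM or more. The depth behind these values is unknown. The 10 most abundant genes took 5.07% to 6.83% of a library and mitochondrially encoded genes 2.16% to 5.27%, and no pair of libraries held identical values.

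Transcripts of liver and kidney genes were present in part of the libraries. ALB, the gene of serum albumin, lay between 80.0 and 418 TPM in 5 of the 8 compound-treated libraries of replicates 1 and 2 and between 101 and 745 TPM in the 6 libraries of replicate 3. It lay between 0.792 and 1.92 TPM in the other 7 libraries, which included each DMSO and each PMA/ionomycin library of replicates 1 and 2. APOA2, a liver apolipoprotein, reached 16.6 to 104 TPM in the same 5 compound-treated libraries and was listed at 0 in replicate 3. UMOD, the kidney gene of uromodulin, reached 8.97 TPM in SP100030 replicate 2, 13.1 TPM in selinexor replicate 1 and 15.8 TPM in activated selinexor replicate 2.

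**Figure D1:**
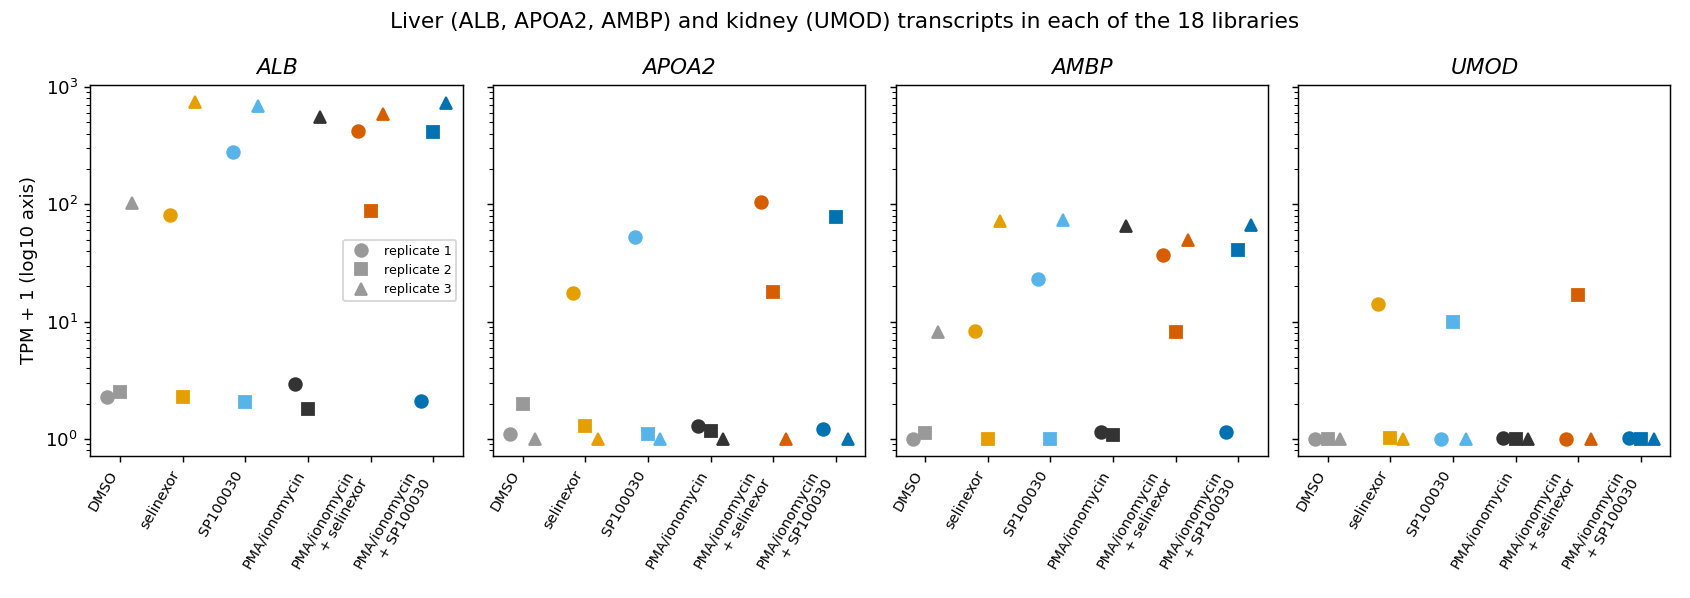
TPM + 1 on a log10 axis of the liver genes ALB, APOA2 and AMBP and the kidney gene UMOD in each of the 18 libraries by group, with the marker shape giving the replicate. ALB lies between 101 and 745 TPM in the libraries of replicate 3 and at 1.92 TPM or less in 7 libraries of replicates 1 and 2.

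PMA/ionomycin was compared with DMSO to find the transcripts that changed in 6 hours of activation. Chemokines and cytokines rose from low levels. CCL4, a chemokine for T cells and monocytes (chromosome 17, 36103590 to 36105621, plus strand), rose from 3.85 ± 4.10 to 716 ± 559 TPM (SD, n = 3), a log2 change of 7.43 ± 0.73 (SE). IL2, the T cell growth factor (chromosome 4, 122451470 to 122456725, minus strand), rose from 0.0354 ± 0.0307 to 5.52 ± 2.44 TPM (log2 change 2.59 ± 0.22, adjusted p = 7.65e-07). TNF rose from 0.204 ± 0.118 to 12.1 ± 3.54 TPM. CD69, an early activation antigen, rose from 12.1 ± 4.29 to 419 ± 159 TPM, and IL2RA, the alpha chain of the IL2 receptor, from 0.333 ± 0.134 to 42.8 ± 10.6 TPM. Of the 21 cytokine and chemokine genes measured 18 rose and 3 did not pass the threshold (19 rose and 1 fell adjusted over the list alone). Of 19 surface activation markers 15 rose (15 rose and 2 fell adjusted over the list alone). The camera adjusted p was 1.79e-26 for the cytokines and 8.18e-19 for the surface markers, and 0.00745 and 0.00539 with an estimated correlation.

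Genes of other lists changed too. Of 27 activation transcription factors 18 rose and 2 fell (18 and 3 adjusted over the list alone; camera adjusted p = 1.22e-19, and adjusted p = 0.00428 with an estimated correlation). EGR1, an immediate early factor, rose from 3.89 ± 2.46 to 237 ± 44.2 TPM and NR4A1 from 8.95 ± 1.98 to 146 ± 36.9 TPM (SD, n = 3). MYC, a growth regulator, fell from 293 ± 34.1 to 73.2 ± 15.4 TPM (log2 change -2.00 ± 0.16). Of 26 NF-kB targets 18 rose (18 rose and 1 fell adjusted over the list alone), with an adjusted p of 1.79e-26, and adjusted p = 0.00539 with an estimated correlation. Among them were the anti-apoptotic gene BCL2A1 (0.858 to 143 ± 17.2 TPM), IER3 (18.8 ± 3.02 to 1172 ± 208 TPM) and the NF-kB inhibitor gene NFKBIA (20.5 ± 1.09 to 148 ± 20.5 TPM). Of 21 MAPK feedback genes 12 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 3.47e-18, and adjusted p = 0.0178 with an estimated correlation). The phosphatase gene DUSP5 rose by a log2 of 5.43 ± 0.24 and RASGRP1 changed by -1.98 ± 0.22. Of 19 genes of the endoplasmic reticulum unfolded protein response 15 rose (15 rose and 1 fell adjusted over the list alone; adjusted p = 3.47e-18, and adjusted p = 0.00539 with an estimated correlation). They included the chaperone gene HSPA5 (102 ± 9.69 to 757 ± 168 TPM) and PDIA4 (25.2 ± 5.11 to 120 ± 7.21 TPM). Of 25 ATF4 and integrated stress response genes 7 rose and 2 fell (8 and 4 adjusted over the list alone, 11 and 6 with the replicate block), with DDIT3 at a log2 change of 2.80 ± 0.28. The list's adjusted p was 0.00147, and adjusted p = 0.417 with an estimated correlation. CDKN1A, a cell cycle inhibitor and p53 target, rose from 4.01 ± 1.63 to 68.4 ± 13 TPM, and 5 of 22 p53 targets rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.216).

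The genes that fell included RAG1 (chromosome 11, 36510709 to 36593156, plus strand) and RAG2, which encode the recombinase of receptor rearrangement. RAG1 fell from 14.6 ± 2.15 to 0.468 TPM (log2 change -3.42 ± 0.21, adjusted p = 2.5e-08) and RAG2 from 16.1 ± 3.27 to 0.846 TPM (SD, n = 3). SELPLG fell from 64.8 to 6.15 TPM and ZFP36L2 from 70.2 to 10.1 TPM. In the T cell receptor and identity list 10 of 29 genes rose and 10 fell (10 and 12 adjusted over the list alone, adjusted p = 0.54). TRAC, the receptor alpha constant region, rose by a log2 of 2.72 ± 0.16. In 5 lists the set test was lower, and each of these calls was lost with an estimated correlation. Heat shock genes fell in 8 of 21 (10 adjusted over the list alone, 14 with the replicate block; adjusted p = 0.000329, and adjusted p = 0.75 with an estimated correlation). DNAJB1 fell from 164 ± 16.7 to 69.1 ± 6.38 TPM. G1/S genes fell in 13 of 28 (14 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.656 with an estimated correlation). G2/M genes fell in 12 of 28 (15 adjusted over the list alone, 20 with the replicate block; adjusted p = 0.000166, and adjusted p = 0.749 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 24 and rose in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.00395, and adjusted p = 0.774 with an estimated correlation). Nuclear transport genes fell in 5 of 33 (5 adjusted over the list alone, 12 with the replicate block; adjusted p = 0.0256, and adjusted p = 0.83 with an estimated correlation). With median-ratio scaling, which moved the median of all genes from -0.13 to -0.00, the numbers that fell were 5 for G1/S, 7 for G2/M, 7 for cholesterol synthesis and 3 for nuclear transport. XPO1 itself (chromosome 2, 61477849 to 61538626, minus strand) was at 55.6 ± 18.4 against 99.2 ± 5.96 TPM (log2 change -0.88 ± 0.28, adjusted p = 0.0423). This call was lost without DMSO replicate 1, 2 or 3 (adjusted p = 0.0940, 0.119 and 0.0895) or PMA/ionomycin replicate 3 (-0.58, adjusted p = 0.166).

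The remaining lists showed no set test call under activation apart from 1. NK cell markers had an adjusted p of 0.00368, and adjusted p = 0.513 with an estimated correlation. Of the 5 measured 1 rose (2 with the replicate block), which was GZMB, the gene of granzyme B (0.993 ± 0.169 to 103 ± 25 TPM, SD, n = 3). Of 21 calcineurin and NFAT genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, 5 and 2 with the replicate block, adjusted p = 0.524). NFATC1 rose by a log2 of 1.62 ± 0.21 and RCAN1, an inhibitor of calcineurin, changed by -1.28 ± 0.19. FOXO and quiescence genes rose in 4 and fell in 5 of 25 (4 and 6 adjusted over the list alone, 4 and 8 with the replicate block, adjusted p = 0.956). Interferon-stimulated genes rose in 5 and fell in 4 of 28 (5 and 5 adjusted over the list alone, adjusted p = 0.672), with GBP2 at 1.69 and RSAD2 at -1.46. BCL2 family genes rose in 3 and fell in 3 of 21 (3 and 4 adjusted over the list alone, 4 and 5 with the replicate block, adjusted p = 0.903). Glycolysis genes rose in 3 and fell in 5 of 22 (3 and 6 adjusted over the list alone, adjusted p = 0.879), with SLC2A3 at 1.84 and SLC2A1 at -2.04, both glucose transporter genes. NRF2 targets rose in 1 and fell in 1 of 23 (1 fell adjusted over the list alone, 1 rose and 5 fell with the replicate block, adjusted p = 0.826). Ribosome biogenesis genes rose in 1 and fell in 4 of 28 (2 and 5 adjusted over the list alone, 2 and 10 with the replicate block, adjusted p = 0.396). None of 13 mitochondrially encoded genes passed in limma (1 rose and 2 fell with the replicate block, adjusted p = 0.465), and the 5 monocyte markers had 1 higher adjusted over the list alone (adjusted p = 0.799). With median-ratio scaling the numbers that fell were 3 for FOXO and quiescence, 2 for interferon-stimulated, 3 for glycolysis and 1 for ribosome biogenesis genes. The 3 B cell and 4 erythroid or epithelial markers measured had no member past the limma threshold and were too few for a set test.

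Activation changed 2099 of the 14141 genes in limma, 756 higher and 1343 lower, of which 434 and 325 changed at least 2-fold. With the replicate block the count was 4030 (1210 higher, 2820 lower), and with only the 2 groups compared in the fit 692 (370 higher, 322 lower). Without PMA/ionomycin replicate 3 it was 2117 (1006 higher, 1111 lower). That library had the lowest median over the tested genes, 9.68 TPM against 11.3 to 15.5 TPM in the others. The share of higher genes depended on scaling, at 36.0% as deposited, 53.8% with median-ratio scaling (991 higher, 851 lower) and 47.8% with quantile scaling (935 higher, 1020 lower). The 3 values of each group did not overlap for 28.3% of genes, where chance gives 10% if libraries are exchangeable. Libraries with the same number deviate together, so 10% is not a matched baseline.

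**Figure D2:**
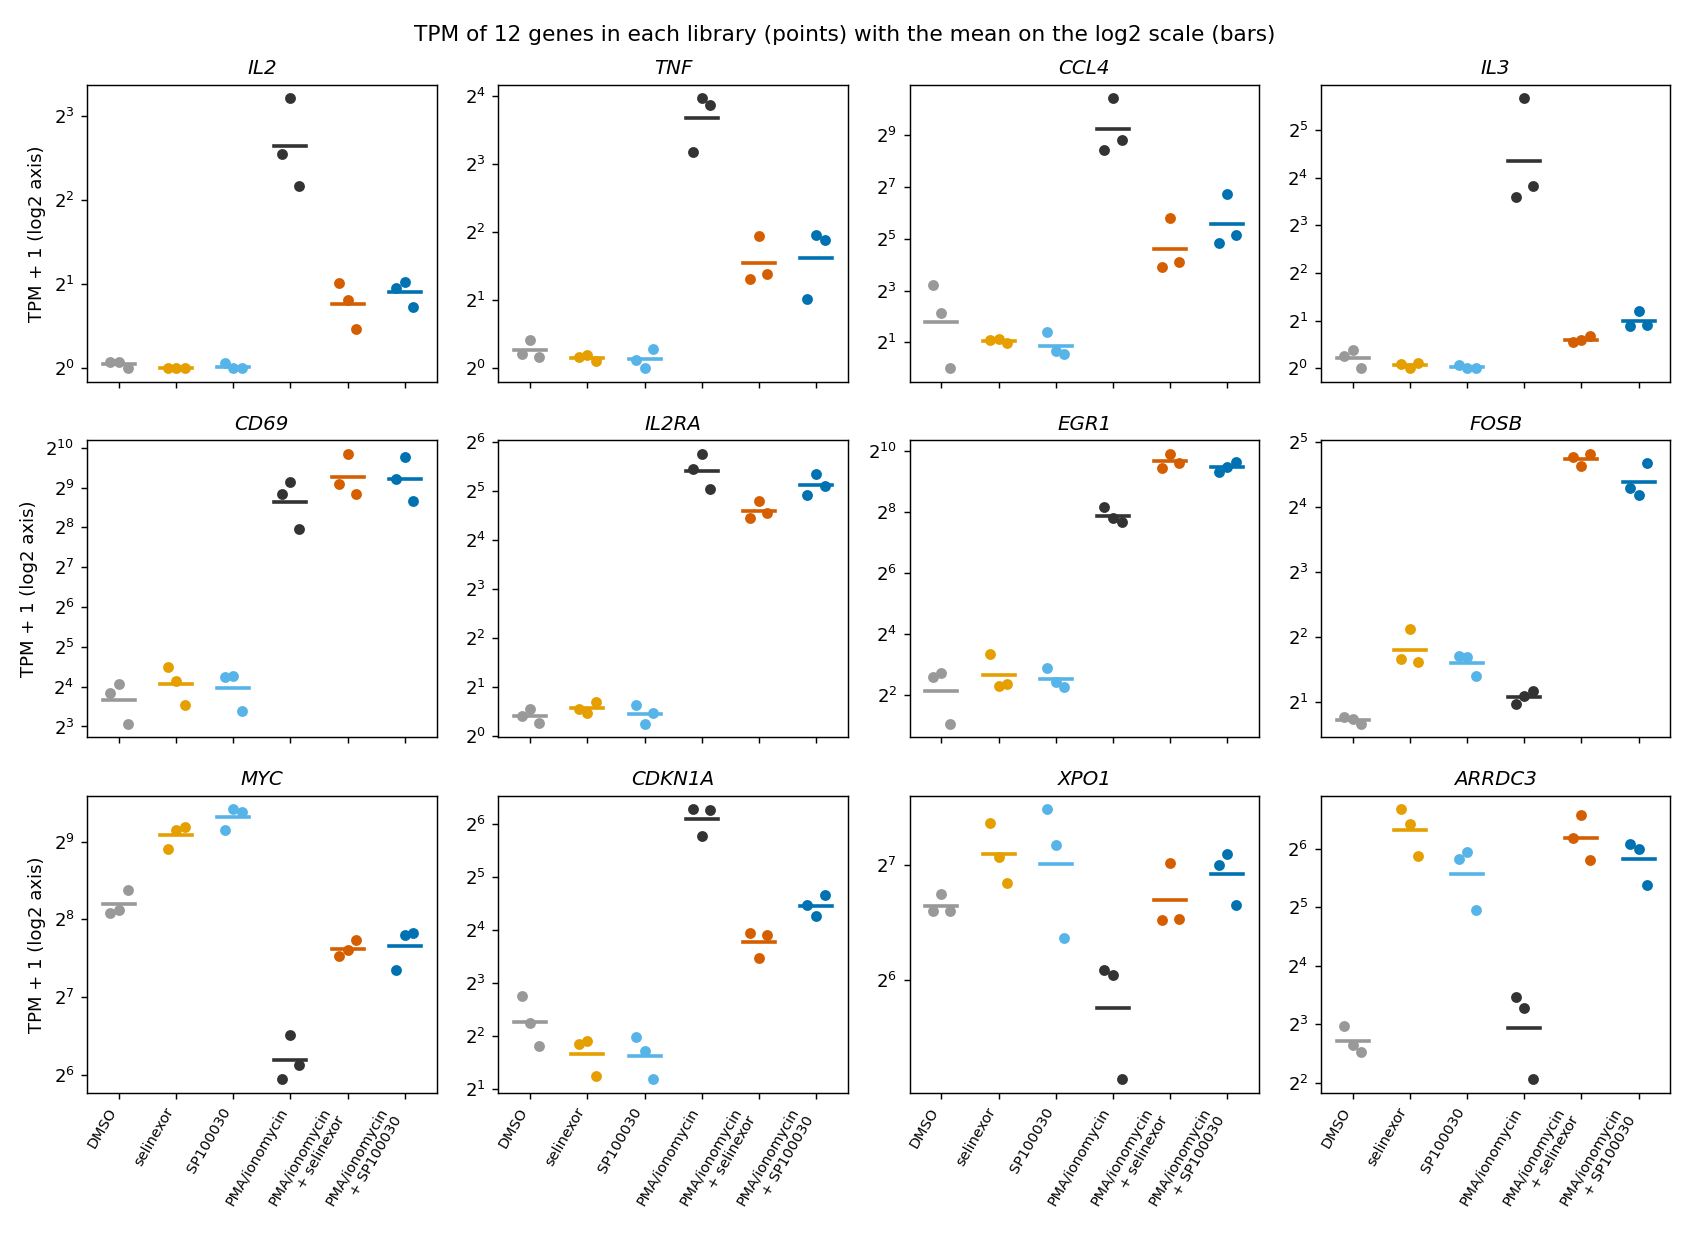
TPM + 1 on a log2 axis of 12 genes in each library of the 6 groups, with bars at the group mean on the log2 scale (n = 3). IL2, TNF, CCL4 and IL3 lie highest with PMA/ionomycin alone, and ARRDC3 is higher in each compound group than in its control.

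Selinexor was compared with DMSO to show its effect in resting cells. Whether its effects come from XPO1 inhibition was not tested. ARRDC3, an arrestin-domain gene (chromosome 5, 91368724 to 91383359, minus strand), rose from 5.62 ± 1.08 to 81.5 ± 22.0 TPM (SD, n = 3; log2 change 3.62 ± 0.36, adjusted p = 7.43e-06). FBXO32, a ubiquitin ligase gene induced by FOXO factors, rose from 1.44 to 11 ± 1.32 TPM, ARID5B from 12.5 to 54.3 ± 11.2 TPM. TNRC6B rose from 5.96 to 25.3 TPM, CREBRF from 1.40 to 8.44 TPM and ANKRD30BL from 6.86 to 43.5 ± 15.6 TPM. CCDC71 fell from 26.1 ± 2.69 to 2.24 ± 0.220 TPM (log2 change -3.06 ± 0.16, adjusted p = 3.98e-08), HSD17B1 from 39.2 ± 0.866 to 4.95 ± 1.12 TPM and TREX1, an exonuclease gene, from 17.3 to 2.46 TPM. THEM6, LDOC1L and the receptor segment TRBV7-2 fell by 2.52, 2.46 and 2.76 on the log2 scale. MYC rose to 542 ± 55.9 TPM and NFKBIA to 38.9 ± 3.69 TPM, while XPO1, at 137 ± 25.1 TPM (log2 change 0.45 ± 0.28, adjusted p = 0.314), and the other 8 panel genes did not pass.

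List members moved both ways under selinexor. ORAI1, a calcium channel gene of the calcineurin list, fell from 50.0 ± 5.27 to 9.68 ± 2.76 TPM (SD, n = 3), and 5 of 21 genes of that list fell. JUND fell from 48.8 ± 6.96 to 13.7 ± 1.64 TPM, with 3 of 27 transcription factors higher and 4 lower (4 and 2 with median-ratio scaling). RRS1, of ribosome biogenesis, fell from 34.7 ± 5.61 to 6.52 ± 0.922 TPM, with 4 of 28 genes of its list lower (9 with the replicate block). BCL2L1, an anti-apoptotic gene, fell from 51.8 ± 6.86 to 23.9 ± 6.29 TPM, with 5 of 21 BCL2 family genes lower (9 with the replicate block). FEN1, a DNA replication nuclease gene, fell from 173 ± 11.6 to 79.6 ± 9.17 TPM, with 8 of 28 G1/S genes lower (5 with median-ratio scaling, adjusted p = 0.0876). BCL11B, a T cell transcription factor gene, rose from 15.1 ± 5.98 to 48.0 ± 2.86 TPM. It was the 1 of 29 receptor and identity genes that rose, and 4 fell (10 with the replicate block, 2 with median-ratio scaling; adjusted p = 0.66). Mitochondrially encoded genes had a median log2 change of 0.62 and 2 of 13 rose (8 adjusted over the list alone, 12 with the replicate block; adjusted p = 6.89e-06, and adjusted p = 0.774 with an estimated correlation). The number was 9 with median-ratio and 0 with quantile scaling, and 0 with replicates 1 and 2 only and 7 with marker covariates, both chosen after seeing the data. MAPK feedback genes rose in 3 of 21 (3 adjusted over the list alone; median 0.04, adjusted p = 0.0429, and adjusted p = 0.774 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0735), with median-ratio scaling (adjusted p = 0.102) and with a pseudocount of 0.1 (adjusted p = 0.0602). Of 25 FOXO and quiescence genes 4 rose (4 adjusted over the list alone; 4 rose and 3 fell with the replicate block; adjusted p = 0.0519). Of 33 nuclear transport genes 1 rose and 7 fell (2 and 7 adjusted over the list alone, 4 and 9 with the replicate block, 3 and 2 with median-ratio scaling; adjusted p = 0.939).

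Selinexor changed 2593 genes in limma, 373 higher and 2220 lower (139 and 772 at least 2-fold), and 4678 with the replicate block (1089 higher, 3589 lower). The share of higher genes was 14.4% as deposited, 38.4% with median-ratio scaling (955 higher, 1531 lower) and 43.6% with quantile scaling (1092 higher, 1411 lower), and median-ratio scaling moved the median of all genes from -0.12 to 0.03. The 5 libraries of replicates 1 and 2 with high ALB included selinexor replicate 1 (80.0 TPM) and SP100030 replicate 1 (275 TPM). With replicates 1 and 2 only, chosen after seeing the data, the count was 3986.

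SP100030 was compared with DMSO in the same way. ARRDC3 rose to 48.9 ± 16.5 TPM (SD, n = 3; log2 change 2.86 ± 0.36, adjusted p = 0.000148), FBXO32 to 7.82 ± 1.32 TPM, TNRC6B to 23.4 TPM, ARID5B to 44.9 TPM and GPCPD1 from 4.86 to 17.1 TPM. CCDC71 fell to 4.99 ± 0.896 TPM and HSD17B1 to 8.02 ± 0.949 TPM (log2 changes -2.18 and -2.16), TREX1 by 2.17 and TRBV7-2 by 2.82 on the log2 scale. MYC rose to 638 ± 60.6 TPM and NFKBIA to 33.7 ± 1.33 TPM, and XPO1, at 134 ± 48.7 TPM (log2 change 0.36 ± 0.28, adjusted p = 0.53), did not pass. JUND fell to 13.1 ± 2.58 TPM, ORAI1 to 18.3 ± 6.09 TPM, RRS1 to 11 ± 1.10 TPM and FEN1 to 98.3 ± 13.8 TPM. BCL11B rose to 40.1 ± 5.58 TPM and NFKBIZ, an atypical NF-kB regulator gene, from 0.476 to 2.89 TPM. Of 29 receptor and identity genes 1 rose and 2 fell (1 and 6 with the replicate block). Of 26 NF-kB targets 2 rose and 0 fell (3 and 4 with the replicate block). Of 27 transcription factors 2 rose and 3 fell (4 and 4 with the replicate block). Lower were 1 of 21 calcineurin genes and 2 of 28 ribosome biogenesis genes (2 and 4 with the replicate block).

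Of 25 FOXO and quiescence genes 3 rose with SP100030 (3 adjusted over the list alone, 6 with the replicate block, 5 with median-ratio scaling; adjusted p = 0.0132, and adjusted p = 0.774 with an estimated correlation). G1/S genes fell in 5 of 28 (6 adjusted over the list alone, 10 with the replicate block, 3 with median-ratio scaling; adjusted p = 0.0227, and adjusted p = 0.774 with an estimated correlation). It lost the call with median-ratio scaling (adjusted p = 0.103). MAPK feedback genes rose in 3 of 21 (adjusted p = 0.0166, and adjusted p = 0.774 with an estimated correlation). Mitochondrially encoded genes had a median log2 change of 0.43 (adjusted p = 0.000329, and adjusted p = 0.774 with an estimated correlation), and none of 13 rose in limma, 8 with the replicate block and 1 with median-ratio scaling. Cytokines (adjusted p = 0.759) and surface markers (adjusted p = 0.689) showed no set test call with SP100030, nor with selinexor (adjusted p = 0.933 for both lists).

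In all, 1325 genes changed with SP100030 in limma, 243 higher and 1082 lower (63 and 375 at least 2-fold), and 2953 with the replicate block (781 higher, 2172 lower). The count was 862 without DMSO replicate 1, 817 without DMSO replicate 2, 878 without SP100030 replicate 1 and 669 without SP100030 replicate 2, and 2256 with replicates 1 and 2 only, chosen after seeing the data. The share of higher genes was 18.3% as deposited, 34.8% with median-ratio scaling (464 higher, 869 lower) and 41.2% with quantile scaling (575 higher, 820 lower).

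Selinexor with PMA/ionomycin was compared with PMA/ionomycin alone to show the effect of selinexor added together with activation. Cytokine transcripts were lower. IL2 fell from 5.52 ± 2.44 to 0.720 ± 0.321 TPM (SD, n = 3; log2 change -1.88 ± 0.22, adjusted p = 3.64e-05), TNF from 12.1 ± 3.54 to 1.97 ± 0.745 TPM. CCL4 fell from 716 ± 559 to 28.2 ± 22.4 TPM and CCL3 from 288 ± 188 to 14.8 TPM. IL3 (chromosome 5, 132060529 to 132063204, plus strand) fell from 24.6 ± 21.7 to 0.519 ± 0.0689 TPM (log2 change -3.75 ± 0.37, adjusted p = 7.29e-06). LTB, the gene of lymphotoxin beta (chromosome 6, 31580525 to 31582522, minus strand), fell from 294 ± 151 to 21.6 ± 7.74 TPM. Of 21 cytokine and chemokine genes 13 fell (16 adjusted over the list alone; median -1.88, adjusted p = 7.25e-11, and adjusted p = 0.126 with an estimated correlation). Of 19 surface markers 13 fell (13 adjusted over the list alone; median -0.78, adjusted p = 0.00022, and adjusted p = 0.315 with an estimated correlation). IL2RA was at 23.5 ± 3.18 against 42.8 ± 10.6 TPM (log2 change -0.82 ± 0.19, adjusted p = 0.00687), a call lost with a pseudocount of 0.1 (adjusted p = 0.0727). CD69, at 641 ± 244 TPM (log2 change 0.63 ± 0.39), had an adjusted p of 0.303, or 0.00586 with the replicate block. Of 26 NF-kB targets 3 rose and 13 fell (3 and 17 adjusted over the list alone; adjusted p = 0.00246, and adjusted p = 0.749 with an estimated correlation). TRAF1 (chromosome 9, 120902393 to 120929173, minus strand) fell from 37.6 ± 3.00 to 4.30 TPM and BCL2A1 from 143 ± 17.2 to 21.7 ± 5.65 TPM, while NFKBIZ rose by a log2 of 2.03 ± 0.25. GZMB fell from 103 ± 25 to 11.4 ± 0.941 TPM.

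FOSB, an AP-1 subunit gene (chromosome 19, 45467995 to 45475179, plus strand), rose from 1.12 ± 0.144 to 25.6 ± 1.76 TPM (SD, n = 3; log2 change 3.65 ± 0.17, adjusted p = 1.31e-08). FOS rose from 5.98 ± 1.86 to 39.0 ± 4.48 TPM and EGR1 from 237 ± 44.2 to 817 ± 131 TPM. Of 27 activation transcription factors 10 rose and 6 fell (10 and 7 adjusted over the list alone, adjusted p = 0.0802). JUND fell from 173 ± 63.2 to 53.6 ± 16.6 TPM and TBX21, the gene of T-bet, from 19.9 ± 11.9 to 4.23 ± 1.25 TPM. ARRDC3 rose from 7.32 ± 3.67 to 74.2 ± 20.1 TPM, SLC39A10 to 87.6 TPM (log2 change 2.24) and NEK11 from 1.79 to 12.9 TPM. MYC (chromosome 8, 127735434 to 127741434, plus strand) rose from 73.2 ± 15.4 to 196 ± 14.6 TPM, and CDKN1A (chromosome 6, 36676460 to 36687339, plus strand) fell from 68.4 ± 13 to 12.8 ± 2.42 TPM. XPO1 was at 104 ± 21.7 against 55.6 ± 18.4 TPM (log2 change 0.93 ± 0.28, adjusted p = 0.0278). It did not pass without PMA/ionomycin replicate 3 (0.62, adjusted p = 0.0991) or activated selinexor replicate 1 (1.02, adjusted p = 0.0508) or 2 (0.77, adjusted p = 0.124). NR4A1, NFKBIA and RCAN1 did not pass, with log2 changes of -0.13, -0.10 and 0.24.

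Cholesterol synthesis genes rose in 7 of 24 and fell in 1 (7 and 1 adjusted over the list alone, 12 and 2 with the replicate block; median 0.28, adjusted p = 0.00235, and adjusted p = 0.774 with an estimated correlation). INSIG1, a sterol sensor, rose from 137 ± 35.3 to 379 ± 39.4 TPM (SD, n = 3). FOXO and quiescence genes rose in 6 and fell in 2 of 25 (6 and 2 adjusted over the list alone, 10 and 3 with the replicate block, 10 and 2 with median-ratio scaling; adjusted p = 0.016, and adjusted p = 0.774 with an estimated correlation). FBXO32 was at 19.0 ± 1.33 against 4.85 ± 1.63 TPM. Heat shock genes rose in 2 of 21 (2 adjusted over the list alone, 5 with the replicate block; adjusted p = 0.0227, and adjusted p = 0.815 with an estimated correlation). Of 22 p53 targets 1 rose and 6 fell (adjusted p = 0.0775). The mitochondrial list passed with the replicate block (adjusted p = 0.0447) and not without it (adjusted p = 0.14). Selinexor changed 2572 genes in activated cells in limma, 714 higher and 1858 lower (234 and 661 at least 2-fold), and 4904 with the replicate block (1943 higher, 2961 lower). With only the 2 groups compared in the fit the count was 820 (137 higher, 683 lower). The count was 1686 without activated selinexor replicate 1, whose ALB was 418 TPM, and 3436 (623 higher, 2813 lower) without PMA/ionomycin replicate 3. The share of higher genes was 27.8% as deposited, 40.5% with median-ratio scaling (1228 higher, 1803 lower) and 47.5% with quantile scaling (1498 higher, 1658 lower).

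SP100030 with PMA/ionomycin was compared with PMA/ionomycin alone. IL2 fell to 0.878 ± 0.199 TPM (SD, n = 3; log2 change -1.74 ± 0.22, adjusted p = 0.000204). TNF fell to 2.20 ± 1.03 TPM, IL3 to 1.01 ± 0.244 TPM, LTB to 32.9 ± 15.4 TPM and CSF2 from 30.2 to 2.32 TPM. CCL4 was at 55.2 ± 42.2 TPM (log2 change -3.65 ± 0.73, adjusted p = 0.00466), a call lost with a pseudocount of 0.1 (adjusted p = 0.0532). Of 21 cytokine and chemokine genes 12 fell (13 adjusted over the list alone; median -1.74, adjusted p = 2.04e-13, and adjusted p = 0.0685 with an estimated correlation). Of 19 surface markers 5 fell (7 adjusted over the list alone; 2 rose and 8 fell with the replicate block; 3 fell with replicates 1 and 2 only; adjusted p = 0.00415, and adjusted p = 0.579 with an estimated correlation). IL2RA was at 34.2 ± 5.36 TPM (log2 change -0.30, adjusted p = 0.33) and CD69 at 623 ± 233 TPM (log2 change 0.58, adjusted p = 0.355, or 0.0108 with the replicate block). Of 26 NF-kB targets 2 rose and 5 fell (3 and 6 adjusted over the list alone, 4 and 7 with the replicate block; adjusted p = 0.0138, and adjusted p = 0.774 with an estimated correlation). BCL2A1 fell to 37.0 ± 6.59 TPM, TRAF1 to 12.1 TPM and GZMB to 18.7 ± 4.94 TPM, and NFKBIZ rose by a log2 of 1.66 ± 0.25. NK cell markers had an adjusted p of 0.0462, with an adjusted p = 0.774 with an estimated correlation, and lost the call with median-ratio scaling (adjusted p = 0.096) and with a pseudocount of 0.1 (adjusted p = 0.0977).

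FOSB rose to 20.1 ± 3.99 TPM with SP100030 in activated cells and ARRDC3 to 56.8 ± 14 TPM. NEK11 rose to 12.5 TPM, ARID5B from 12.1 to 56.1 TPM and KLF10 from 38.5 ± 9.90 to 143 ± 10.5 TPM (SD, n = 3). EGR1 rose to 718 ± 75.6 TPM and MYC to 203 ± 35.2 TPM, and CDKN1A fell to 21.1 ± 3.06 TPM, with 1 of 22 p53 targets higher and 3 lower (5 and 4 with the replicate block). Of 27 transcription factors 8 rose and 6 fell (11 and 8 adjusted over the list alone, 12 and 7 with the replicate block, adjusted p = 0.238). Cholesterol synthesis genes rose in 8 of 24 (12 adjusted over the list alone; 14 rose and 2 fell with the replicate block; adjusted p = 0.00368, and adjusted p = 0.774 with an estimated correlation). INSIG1 was at 409 ± 71.9 TPM. FOXO and quiescence genes rose in 8 and fell in 1 of 25 (11 and 1 adjusted over the list alone, 13 and 2 with the replicate block; adjusted p = 0.00147, and adjusted p = 0.774 with an estimated correlation). S1PR1, the receptor for T cell egress, rose from 3.16 ± 0.967 to 9.19 ± 2.03 TPM. Heat shock genes rose in 3 of 21 (3 adjusted over the list alone, 7 with the replicate block; adjusted p = 0.0385, and adjusted p = 0.83 with an estimated correlation). Their call was lost with median-ratio scaling (adjusted p = 0.14). XPO1 was at 121 ± 18.7 TPM (log2 change 1.16 ± 0.28, adjusted p = 0.0138), a call lost without activated SP100030 replicate 1 (1.12, adjusted p = 0.0532) or 2 (1.06, adjusted p = 0.0640). RCAN1 had a log2 change of 0.40 (adjusted p = 0.182, or 0.0441 with the replicate block), and NR4A1 and NFKBIA did not pass (-0.52 and -0.10).

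SP100030 changed 1641 genes in activated cells in limma, 806 higher and 835 lower (259 and 258 at least 2-fold), and 4480 with the replicate block (2752 higher, 1728 lower). With only the 2 groups compared in the fit it was 15 (4 higher, 11 lower). The balance of higher and lower genes changed with single libraries. It was 499 higher and 1094 lower without PMA/ionomycin replicate 3, and 903 and 602 without replicate 2. The count was 869 without activated SP100030 replicate 1 and 820 without replicate 2, whose ALB was 415 TPM, and 2492 with replicates 1 and 2 only, chosen after seeing the data. With median-ratio scaling 42.5% were higher (878 higher, 1188 lower), against 49.1% as deposited.

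**Figure D3:**
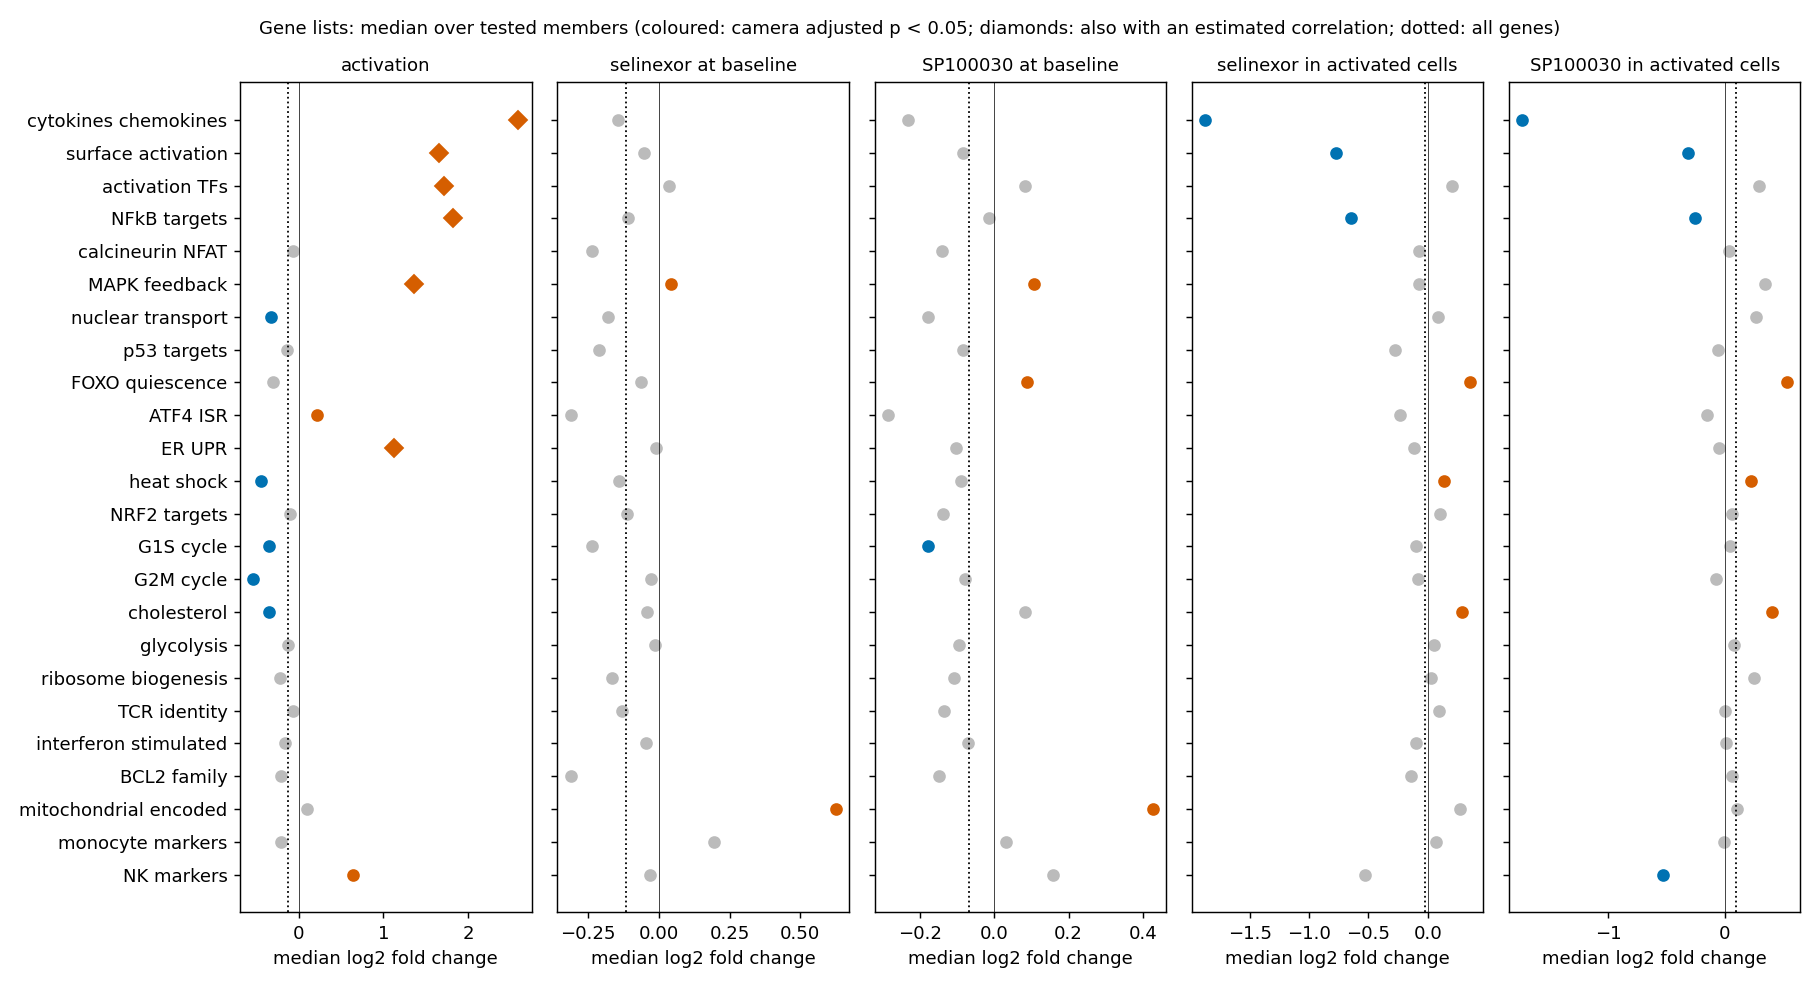
Median log2 fold change of 24 gene lists in the 5 comparisons of a treated group with its control. Red (higher) and blue (lower) points have a camera adjusted p under 0.05, diamonds hold with an estimated correlation, and dotted lines mark the median of all genes. The cytokine list lies at 2.59 under activation and at -1.88 and -1.74 with selinexor and SP100030 in activated cells.

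SP100030 and selinexor were compared directly at the same dose of 1 uM and the same 6 hours. In resting cells 3 genes differed in limma, and each was higher with SP100030. Among them were TGIF2 (13.6 against 6.86 TPM) and C14orf169 (20.9 against 11.5 TPM), with log2 differences of 0.90 and 0.81 and an adjusted p of 0.0461 each. The 3 calls were lost on leaving out any of the 6 libraries of both groups (SP100030 or selinexor replicate 1, 2 or 3), with adjusted p from 0.0641 to 0.285. Both TGIF2 and C14orf169 were also lost with median-ratio scaling (adjusted p = 0.0677). The unadjusted limma p was under 0.05 for 813 of the 14141 genes. The 3 values of each group did not overlap for 10.7% of genes (16.3% in activated cells). Chance gives 10% only if libraries are exchangeable. Libraries with the same number deviate together here, so 10% is not a matched baseline and the share does not show that the compounds act alike. With the replicate block 176 genes passed (166 higher, 10 lower), and 0 with only the 2 groups compared in the fit. The set test of mitochondrially encoded genes was lower with SP100030 (median -0.18, adjusted p = 0.00253, and adjusted p = 0.83 with an estimated correlation). None of them passed toward lower in limma. With the replicate block the G2/M list (adjusted p = 0.0307 against 0.0527) and the BCL2 family (adjusted p = 0.0447 against 0.0878) also passed. The panel had no gene past the threshold, with ARRDC3 at a difference of -0.75. The 95% interval of the difference lay within a log2 of 1 on either side of 0 for 85.6% of the genes. This share is over all tested genes, most of which passed with neither compound. It was not computed for the genes that the compounds changed, so it does not show equal effects.

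In activated cells 30 genes differed, 27 higher and 3 lower with SP100030. TRAF1 was at 12.1 against 4.30 TPM (log2 difference 1.31 ± 0.15, adjusted p = 0.00195). SDHAF2, a mitochondrial assembly factor gene, was at 34.0 ± 1.46 against 16.2 ± 1.75 TPM (SD, n = 3; 1.03 ± 0.12, adjusted p = 0.00195). CRK, EFNA4, ADORA2B and IL21R were higher by 1.17, 1.09, 1.05 and 1.05. The call of CRK was lost without any of the 6 libraries (adjusted p from 0.0505 to 0.124). Those of EFNA4 (0.0565 to 0.128) and ADORA2B (0.0550 to 0.0914) were lost without any but SP100030 replicate 1, and that of IL21R without SP100030 replicate 2 or 3 or selinexor replicate 1 (0.0725, 0.0814 and 0.0764). EFNA4 was also lost with median-ratio scaling (adjusted p = 0.179) and IL21R with a pseudocount of 0.1 (adjusted p = 0.0599). None of the 3 lower genes met the naming rule. The panel had no gene past the threshold, with CDKN1A at 0.68 ± 0.27 (adjusted p = 0.385), IL2RA at 0.52 (adjusted p = 0.331) and IL2 at 0.14 (adjusted p = 0.922). The set test of surface markers was higher with SP100030 (median 0.28 as deposited and 0.13 with median-ratio scaling, adjusted p = 0.00272). This call was lost with an estimated correlation (adjusted p = 0.513). The set test of NF-kB targets was higher too (median 0.31, adjusted p = 0.0207). That call was lost with an estimated correlation (adjusted p = 0.774), with the replicate block (adjusted p = 0.0608) and with median-ratio scaling (adjusted p = 0.0756). The set test of mitochondrially encoded genes was lower (median -0.16, adjusted p = 0.000586, and adjusted p = 0.774 with an estimated correlation), with none of them past the limma threshold toward lower.

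The count of 30 in activated cells was 404 with the replicate block (392 higher, 12 lower) and 0 with only the 2 groups compared in the fit. It was 4 without SP100030 replicate 2, 4 without SP100030 replicate 3, 4 without selinexor replicate 1, 9 without selinexor replicate 2 and 14 without selinexor replicate 3. With median-ratio scaling, which moved the median of all genes from 0.14 to 0.00, 12 genes were higher and 4 lower, and with quantile scaling 4 and 3. The 95% interval of the difference lay within a log2 of 1 on either side of 0 for 79.9% of the genes, again over all tested genes and not those that the compounds changed.

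The interaction of selinexor with activation was tested to ask whether its effect differed between activated and resting cells, and 69 genes passed, 25 higher and 44 lower (247 with the replicate block, 125 and 122). FOSB (2.58 ± 0.25, adjusted p = 9.74e-05), FOS (1.97) and JUN (1.82) were more positive in activated cells, and IL3 (-3.61) and CCL3L3 (-3.56) more negative. IL2 passed toward lower too (adjusted p = 0.0159) and is given no fold, since it is listed at 0 in the 3 resting selinexor libraries. With a pseudocount of 0.1 the calls of FOS (adjusted p = 0.264), IL2 (0.333), IL3 (0.0537) and CCL3L3 (0.129) were lost and 26 genes passed. TNF had -2.02 ± 0.37 (adjusted p = 0.0221). Its call was lost with a pseudocount of 0.1 (0.459) and without DMSO replicate 1 (0.0624) or 3 (0.0623), selinexor replicate 1 (0.0562), 2 (0.0654) or 3 (0.0528), PMA/ionomycin replicate 2 (0.0649), or activated selinexor replicate 1 (0.0777) or 3 (0.0734). CDKN1A had -1.71 (adjusted p = 0.0694, or 0.0134 with the replicate block). The list medians were -1.61 for cytokines (-1.55 without IL2 and CCL20, listed at 0 with selinexor in resting cells; adjusted p = 4.28e-30, and adjusted p = 0.00547 with an estimated correlation) and -0.43 for surface markers (adjusted p = 3.77e-10, and adjusted p = 0.0329 with an estimated correlation). For NF-kB targets the median was -0.45 (-0.44 without CCL20; adjusted p = 9.12e-13, and adjusted p = 0.0467 with an estimated correlation). Of these lists 7, 1 and 3 members were lower (13, 8 and 6 adjusted over the list alone; 11, 5 and 5 with the replicate block). With replicates 1 and 2 only, chosen after seeing the data, 0 cytokine genes and 1 NF-kB target were lower. Cytokine genes such as IL2 (0.0354 TPM) and TNF (0.204 TPM) lay near 0 in DMSO, which leaves little room for a fall in resting cells on this scale. The set tests were therefore repeated with a pseudocount of 0.1, chosen after seeing the data. This does not remove the limit, since IL2 in DMSO lay below 0.1 TPM. The cytokine list then had a median of -2.10 (-1.67 without IL2 and CCL20; adjusted p = 5.60e-22, and adjusted p = 0.00639 with an estimated correlation), and in resting cells its median change with selinexor was -0.45 (-0.46 without them). Surface markers (adjusted p = 8.19e-08) and NF-kB targets (adjusted p = 2.30e-10) kept the call only without an estimated correlation (adjusted p = 0.0706 and 0.0919 with it). Median-ratio scaling moved the median of all genes in this comparison from 0.11 to 0.00. With only the 4 groups compared in the fit 33 genes passed. The count was 34 to 44 on leaving out any of the 12 libraries of the 4 groups other than PMA/ionomycin replicate 1 or 3 or activated selinexor replicate 2.

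The interaction of SP100030 with activation passed for 12 genes, 4 higher and 8 lower (103 with the replicate block, 57 and 46). FOSB had 2.42 ± 0.25 (adjusted p = 0.000685). IL2 had -1.71 (adjusted p = 0.0596, or 0.0106 with the replicate block), TNF -1.93 (0.0676, or 0.0106) and NFKBIA -0.79 (0.223, or 0.0121). Cytokines had a median of -1.38 (adjusted p = 1.79e-26, and adjusted p = 0.00745 with an estimated correlation), with 1 member lower (11 adjusted over the list alone, 7 with the replicate block, 4 with median-ratio scaling). With a pseudocount of 0.1 their median was -1.58 (adjusted p = 4.99e-18, and adjusted p = 0.0136 with an estimated correlation). NF-kB targets had a median of -0.26 (adjusted p = 6.38e-08, and adjusted p = 0.174 with an estimated correlation). With median-ratio scaling, which moved the median of all genes from 0.19 to 0.01, 6 genes were higher and 27 lower. With only the 4 groups compared in the fit 1 gene passed, and with a pseudocount of 0.1 also 1. The count was 2 or 3 without DMSO replicate 1, 2 or 3, SP100030 replicate 1, 2 or 3, PMA/ionomycin replicate 2, or activated SP100030 replicate 1, 2 or 3, and 34 without PMA/ionomycin replicate 1.

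The size of the activation response was compared with and without each compound over the 759 genes that activation changed at least 2-fold. The slope of the response with selinexor on that without it was 0.602 and the median ratio 0.532, and with SP100030 they were 0.702 and 0.623. Choosing genes by their response lowers these values, and simulations with no compound effect gave a slope of 0.924 and a ratio of 0.938. Of the 434 genes that activation raised, 84.8% responded less with selinexor and 76.0% with SP100030, against 60.3% in the simulations. Of the 325 that it lowered, 99.4% and 97.8% did, against 68.8%. The simulations hold no shift of all genes, while the interaction medians of all genes were 0.11 and 0.19 as deposited. Such a shift alone makes lowered genes respond less, so 68.8% is not a matched baseline. The shares were not computed with median-ratio scaling, which gave slopes of 0.611 and 0.693 and ratios of 0.559 and 0.653. Within replicates 1, 2 and 3 the slope was 0.603, 0.612 and 0.538 with selinexor and 0.695, 0.703 and 0.644 with SP100030.

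The effects of both compounds were compared across genes, which are not independent replicates. In resting cells the log2 changes had a Pearson r of 0.891 (covariance 0.204), against an r of 0.502 and a covariance of 0.0530 simulated for unchanged groups against the same controls with the spread of the fit without the block. In activated cells r was 0.885 (covariance 0.247), against 0.499 and 0.0527. Within replicates 1, 2 and 3 r was 0.817, 0.817 and 0.826 in resting and 0.686, 0.812 and 0.893 in activated cells. With the smaller spread of the blocked fit the simulated values were 0.501 and 0.0266 in resting and 0.500 and 0.0265 in activated cells. In resting cells 186 genes were higher with both compounds, where independent lists would share 6.41, and 1043 were lower with both, where they would share 170. In activated cells the numbers were 516 against 40.7 and 782 against 110. No gene passed in opposite directions in limma. The simulations of unchanged groups gave 0 shared calls, and since such groups give few calls at all this is no baseline for the overlaps. Part of the excess over independent lists may come from the shared control libraries. Liver transcripts can add to r and the overlaps too. In resting replicate 1 ALB was at 275 TPM with SP100030 and 80.0 TPM with selinexor, against 1.28 TPM in DMSO. In resting replicate 2, where r was 0.817, it was at 1.06, 1.26 and 1.53 TPM. The r and the overlaps were not computed with marker covariates or without liver and kidney genes.

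**Figure D4:**
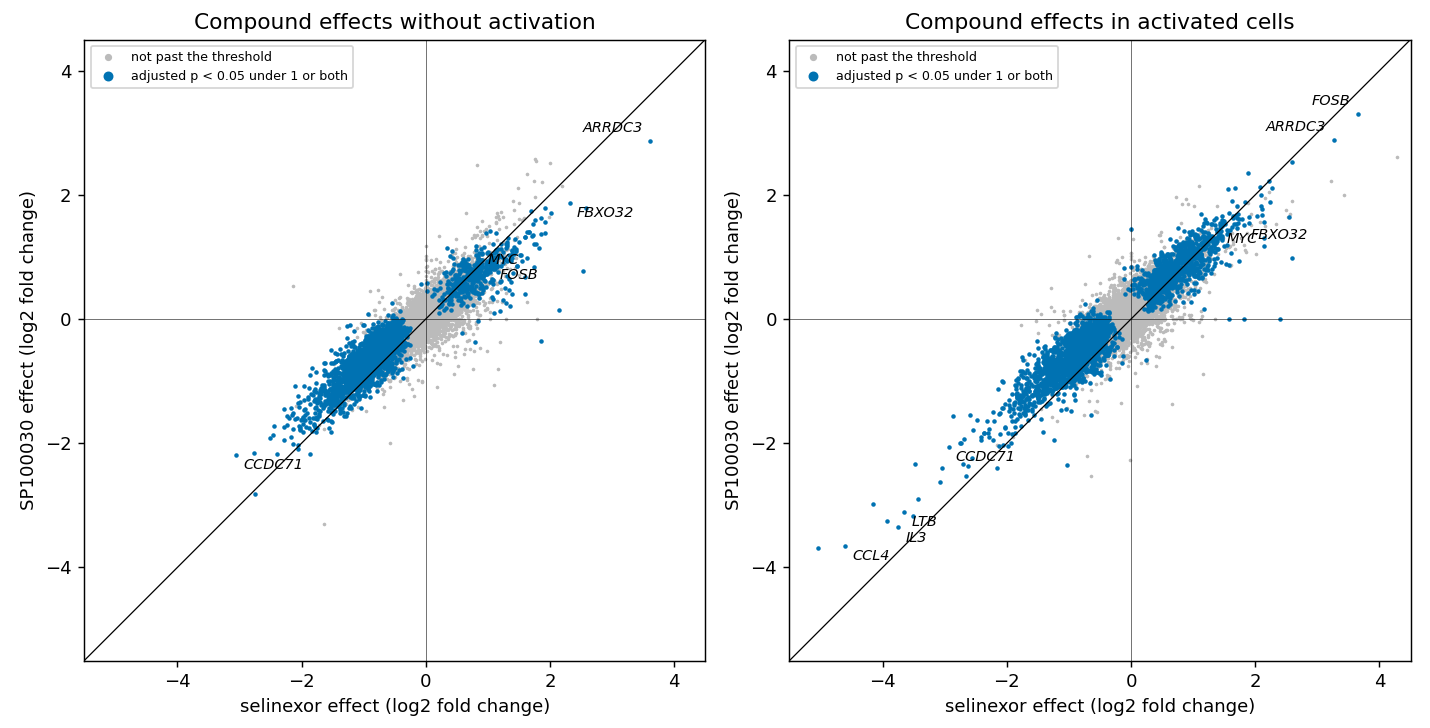
Log2 fold change of each tested gene with SP100030 against that with selinexor, in resting and in activated cells, with the identity line; blue points have an adjusted p under 0.05 with at least 1 compound. The Pearson r across genes is 0.891 in resting and 0.885 in activated cells.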

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

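The tests of compound induction and of the replicate 3 libraries as to the liver transcripts and the list tests with a pseudocount of 0.1 were chosen only after the result was seen; the other tests in this part were planned before it.

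The effect of each compound differed between activated and resting cells, by an interaction term, for 69 genes with selinexor and 12 with SP100030. With selinexor IL2, listed at 0 in the 3 resting selinexor libraries and so given no fold, passed toward lower (adjusted p = 0.0159). The difference was -2.02 for TNF, -0.99 for NFKBIA, 2.58 for FOSB, 1.97 for FOS, 1.82 for JUN, 1.66 for BHLHE23, -4.61 for CCL4L2, -3.61 for IL3, -3.56 for CCL3L3 and -3.37 for CSF2 on the log2 scale. The call of CSF2 was lost without DMSO replicate 3 (adjusted p = 0.0525), selinexor replicate 3 (0.0528) or activated selinexor replicate 1 (0.0545) or 3 (0.0518). The call of NFKBIA (adjusted p = 0.0329) was lost without any of the DMSO or selinexor libraries, PMA/ionomycin replicate 2, or activated selinexor replicate 1 or 3, with adjusted p from 0.0528 to 0.126. The call of TNF was lost without DMSO replicate 1 (0.0624) or 3 (0.0623), selinexor replicate 1 (0.0562), 2 (0.0654) or 3 (0.0528), PMA/ionomycin replicate 2 (0.0649), or activated selinexor replicate 1 (0.0777) or 3 (0.0734). The count of 69 was 34 to 44 on leaving out any of the 12 libraries of the 4 groups other than PMA/ionomycin replicate 1 or 3 or activated selinexor replicate 2.

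With SP100030 the difference was 2.42 for FOSB, 1.53 for FOS, 1.37 for LAIR1, 0.85 for DNAJB1, -3.17 for IL3, -2.40 for the pseudogene FRG2FP and -1.79 for GPR84. The calls of FOS, LAIR1, DNAJB1, IL3, FRG2FP and GPR84 were lost without any DMSO, SP100030 or activated SP100030 library. Those of FOS, LAIR1, DNAJB1, FRG2FP and GPR84 were also lost without PMA/ionomycin replicate 2, those of FOS and DNAJB1 without replicate 3 and that of FRG2FP without replicate 1, with adjusted p from 0.0578 to 0.167. The count of 12 was 2 or 3 without DMSO replicate 1, 2 or 3, SP100030 replicate 1, 2 or 3, PMA/ionomycin replicate 2, or activated SP100030 replicate 1, 2 or 3, and 34 without PMA/ionomycin replicate 1. With a pseudocount of 0.1 the counts were 26 and 1.

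For the gene lists the median difference with selinexor was -1.61 for cytokines (-1.55 without IL2 and CCL20, listed at 0 in a group), -0.43 for surface markers, -0.45 for NF-kB targets, 0.0078 for MAPK feedback genes, -0.094 for the unfolded protein response, 0.29 for heat shock, -0.078 for G2/M, 0.31 for cholesterol synthesis, -0.33 for mitochondrially encoded genes and -0.36 for NK cell markers. The MAPK median was above 0 while the list's mean (-0.16) and its test were lower, and the call (adjusted p = 0.0276) was lost with the replicate block (0.0608) and with a pseudocount of 0.1 (0.0643). With SP100030 the median was -1.38 for cytokines, -0.26 for surface markers, -0.26 for NF-kB targets, -0.071 for the unfolded protein response (its mean was 0.03 and its test lower), 0.31 for heat shock, -0.021 for G2/M, 0.29 for cholesterol synthesis, -0.31 for mitochondrially encoded genes and -0.40 for NK cell markers. With an estimated correlation, of these lists cytokines, surface markers and NF-kB targets kept the call with selinexor and cytokines with SP100030. With a pseudocount of 0.1 and an estimated correlation only cytokines kept it, in both interactions. That pseudocount leaves little room for a fall in resting cells too, since IL2 in DMSO lay below 0.1 TPM. The ribosome biogenesis list passed in the selinexor interaction with the replicate block (adjusted p = 0.0115 against 0.054).

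Liver and kidney transcripts were high in part of the libraries. In the DMSO and PMA/ionomycin libraries of replicates 1 and 2, ALB, APOA2 and UMOD were at 1.92 TPM or less. Lists of further liver genes (22, of which 3 are expressed in DMSO replicates 1 and 2) and kidney genes (12, of which 1 is) were written before they were tested. Within replicates 1 and 2, in 8 cases, 5 libraries for liver and 3 for kidney, a library with the first markers also had the higher median of its list, at least 1.29 against at most 0.283 for liver and 0.772 against 0.152 for kidney. This is consistent with RNA or reads from liver and kidney material in these libraries. In replicate 3 the median of the second liver list ran from 0.230 TPM, in the DMSO library, to 1.54 TPM. The other 19 liver genes of the first list had a median of at most 0.686% of ALB there, with an SE of 0.634, against at least 5.66% in the 5 libraries. The tables thus argue against the same liver material in replicate 3, where the origin stays open. Induction by the compounds is argued against by ALB at 1.06 TPM in the lowest compound-treated library, with 3 of the 12 compound-treated libraries at or below the 1.92 TPM of a PMA/ionomycin library. At which step such material entered stays open.

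The libraries of replicate 3 stood apart from the others, with a median correlation of 0.731 between their deviations from the group means. A trend with transcript length or GC content does not account for this, since the median correlation was 0.665 after the trend was removed, and the trend held at most 39.0% of a library's deviation. The first principal component, with 28.2% of the variance, separates replicate 3, but not replicate alone. Within replicates 1 and 2 it also parts compound-treated libraries (17.6 to 35.0) from those without compound (-2.90 to -0.0787). A difference in culture, handling or sequencing between the replicates stays open, since the labels record none, and no biological explanation was tested.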

How the results depend on the processing

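The marker-covariate fit, the fit of replicates 1 and 2 only and list tests with a pseudocount of 0.1 were chosen after seeing the data; the others were planned. Counts of changed genes are given in the order activation, selinexor and SP100030 in resting cells, selinexor and SP100030 in activated cells, direct comparison in resting and in activated cells, and selinexor and SP100030 interaction. With the replicate block, which pairs libraries by number, the 9 counts were 4030, 4678, 2953, 4904, 4480, 176, 404, 247 and 103. The block ended no call of a gene named by the rule and added 40, and among the panel genes and the list tests it changed no call other than those given beside the results. The other values that moved by over 1.5 times were these. Fitting only the groups compared gave 692 for activation, and 820 and 15 for selinexor and SP100030 in activated cells. It gave 0 and 0 for the direct comparisons (limma unadjusted counts 813 and 1348 in the full fit) and 33 and 1 for the interactions. Such fits have fewer libraries to estimate the spread. In resting cells they gave 2889 with selinexor and 1292 with SP100030, so fewer libraries alone do not account for these drops. The full fit gives a gene the same spread in all groups, an assumption that was not tested. PMA/ionomycin replicate 3 lay at -78.2 on the first principal component, against -37.4 for the next lowest library. If the PMA/ionomycin libraries spread more widely, the full fit makes p-values of comparisons with that group too small. A minimum log2 change of 1 gave 759, 911, 438, 895, 517, 1 and 10 for the 7 comparisons of groups. A pseudocount of 0.1 gave 10 for the direct comparison in resting cells and 26 and 1 for the interactions. No filter gave 11 and 20, a minimum of 5 TPM 9 and 2, and no trend 9 and 21, for the direct comparison in resting cells and the SP100030 interaction. Median-ratio scaling gave 16 and 33 and quantile scaling 7 and 24 for the direct comparison in activated cells and the SP100030 interaction. Replicates 1 and 2 gave 3986 and 2256 in resting cells, 2492 for SP100030 in activated cells, 0 and 9 for the direct comparisons and 12 and 1 for the interactions. Marker covariates gave 3226 for activation, 3670 for SP100030 in activated cells, 60 and 56 for the direct comparisons and 128 and 28 for the interactions. The cause was not tested for any of these except where a fold limit set it.

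Leaving out each library in turn gave 1420 to 2117, 1782 to 2452, 669 to 1143, 1686 to 3436, 820 to 1884, 0 to 0, 4 to 24, 34 to 87 and 2 to 34 genes in the same order. The slope of the activation response ranged from 0.559 to 0.619 with selinexor (ratio 0.471 to 0.557) and from 0.643 to 0.728 with SP100030 (ratio 0.524 to 0.649). The r of the compound effects ranged from 0.833 to 0.902 (covariance 0.192 to 0.225) in resting and from 0.822 to 0.902 (covariance 0.230 to 0.306) in activated cells. Genes with a log2 response of at least 2 gave slopes of 0.644 and 0.755 and ratios of 0.629 and 0.771. A pseudocount of 0.1 gave an r of 0.839 and covariances of 0.383 and 0.434. Of 55 list calls, 10 held with an estimated correlation, 52 with the block, 48 with median-ratio scaling, 52 with a pseudocount of 0.1 and 8 with both that and an estimated correlation. Of 377 named gene calls, 36 were lost with a pseudocount of 0.1, 35 with median-ratio scaling and 119 without some library, and none reversed.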

Other observations

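The splits of the interactions with additive effects removed and both tests of tissue markers against the few-exon pattern were chosen only after the result was seen; the other tests in this part were planned before it.

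Genes with few exons were lower with both compounds. Genes with 1 or 2 exons had a median log2 change of -0.57 and -0.58 with selinexor in resting cells, against -0.03 for genes with 17 or more exons. Of them 45.1% and 47.5% were called lower in limma, against 6.28%, and 7.39% and 1.45% were called higher, against 2.21%. With SP100030 in resting cells the medians were -0.49 and -0.44 against -0.02. In activated cells they were -0.42 and -0.44 against 0.07 with selinexor, and -0.26 and -0.29 against 0.21 with SP100030. Activation alone gave -0.09 and -0.14 against -0.13.

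Transcript length, GC content and RNA from other tissue were tested as explanations of this pattern, over the 12184 tested genes (86.2%) with a known exon number, of which 836 have 1 or 2 exons. The tables argue against each as the whole cause. Averaged over 5 classes of transcript length, or over 5 classes of GC content, the few-exon genes stayed lower than the other genes with both compounds. The weakest average among the 12 same-numbered pairs of libraries was -0.390 for length and -0.349 for GC content. Values of single classes are not given. In the 2 pairs of libraries low in liver and kidney markers, of selinexor in resting and SP100030 in activated cells, the difference without classes was -0.383 at its weakest. The other 2 comparisons have no such pair. Fits of all 12 pairs on their differences in ALB and UMOD, with or without APOA2, put the few-exon difference at equal marker levels at -0.404 or lower there, with an SE of 0.0401 or less. The pairs use each control library for both compounds, so they are not independent and this SE is only approximate. An effect of the compounds on transcripts that undergo little splicing remains a hypothesis, since it was found and tested in the same libraries.

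The real count of changed genes was compared with other splits of the same libraries. For the 7 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes, and 3 against 3 libraries cannot give a share under 0.1. The real and highest other counts were 2099 and 1 for activation, 2593 and 1 for selinexor and 1325 and 1 for SP100030 in resting cells. They were 2572 and 366 for selinexor and 1641 and 1 for SP100030 in activated cells, and 3 and 0 and 30 and 0 for the direct comparisons in resting and activated cells. The split with 366 keeps replicate 3 together. Among the 4 splits that part all 3 pairs, as the real one does, the highest other count was 1. For the interactions, 10 of 100 drawn splits gave at least 69 genes with selinexor (highest 1734) and 8 of 100 gave at least 12 with SP100030 (highest 2940), so chance was not excluded by these splits. Those that exchange compound labels within a state carry the compound's own effect. With the additive effects removed, 1 of 100 splits, the real one, gave as many, with highest other counts of 2 and 1. These effects were removed by the real labels and the real interaction was left in. The real split and the others were thus not on equal terms, so this cannot decide whether chance gave the counts.

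The median of the mean TPM was 0.357 for the monocyte, 0.152 for the B cell, 0.305 for the erythroid and epithelial and 0.545 for the NK cell markers. The highest mean TPM was 440 for AIF1 among the monocyte markers, 124 for CD79A among the B cell markers, 50.7 for HBB among the erythroid and epithelial markers and 22.8 for GZMB among the NK cell markers.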
